A study of Caldicellulosiruptor saccharolyticus with 5 samples.

How the data were processed

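RNA from Caldicellulosiruptor saccharolyticus, an anaerobic bacterium that grows at 70 °C and uses plant polysaccharides, was measured on 5 spotted 2-colour arrays. The labels give 5 growth substrates, glucose, xylose, xylan, xyloglucan and xyloglucan oligosaccharides, each at 0.5 g per litre, with cells passed 7 times on a substrate before the culture that was harvested in mid-logarithmic growth. Each array compared 2 substrates, and the 5 arrays closed a loop: xyloglucan in Cy3 with xyloglucan oligosaccharides in Cy5, xyloglucan oligosaccharides with xylose, xylose with glucose, glucose with xylan, and xylan with xyloglucan. Each substrate was therefore measured in 2 channels, 1 of each dye. The labels do not say whether those 2 channels came from separate cultures, so the p-values may measure only the spread between hybridisations.

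The deposited scanner files hold, per the file headers, the mean intensity of each spot and of its local background in both channels. They carry no normalization and no spot flags, and the scanner software is not given in the sources used here. Channel 1 is Cy3 and channel 2 is Cy5 per the labels. Each array has 15552 spots, of which 1587 are named as empty and the rest hold 2793 probes with 5 spots each. Of the probes, 2695 carry a Csac locus tag and 98 another name. The files do not pair the tags with gene names or products, and no reference annotation was used here, so genes are given by locus tag. The deposited series table holds log2 ratios that the authors computed. How they were made is not given in the sources used here, and scale and direction were found by setting the table against the scanner values. Each of its columns correlated across probes at 0.99 to 0.994 with median-centred, loop-fitted ratios of the same array, in base 2 and as channel 1 over channel 2. That direction opposes the Cy5 over Cy3 direction used below for single arrays. The column medians were -0.09, 0.02, 0.05, -0.1 and 0.08 in the array order above. Its rows are values fitted over the loop, so it served only as an alternative for values without a test.

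Background was corrected with limma 3.58.1 in R 4.3.3 (normexp, offset 50), and log2 ratios of Cy5 over Cy3 were normalized within each array by loess with the empty spots at weight 0. The 5 spots of a probe were averaged. No scaling between arrays was applied. A linear model with glucose as the reference was fitted to the 5 ratios of each probe. It estimates 4 contrasts and leaves 1 residual degree of freedom, the closure of the loop, which limma's empirical Bayes step moderated across probes (prior degrees of freedom 9.59, prior SD 0.54). A constant dye effect of a gene cancels in every contrast and enters the residual. It does not cancel in a value that leaves out an array, so such values can differ by dye alone. A comparison of 2 substrates that share an array has a standard error factor of 0.894, and of 2 that do not, 1.1. Every comparison combines 2 ways round the loop, a shorter and a longer one, and 1 or both are given for printed genes named by the rule where 1 of them differed from the fitted log2 value by more than 1.5 times, apart from genes given by direction only. The p-values were adjusted by Benjamini-Hochberg over the 2793 probes, with a threshold of 0.05. All log2 differences are the first named substrate minus the second, with the standard error of the fit.

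A probe was called above background in a channel when the median of its spots exceeded the median of the empty spots by 3 scaled median absolute deviations. Where a probe was above background in neither channel of a substrate, the difference is given as a bound ("at least N-fold"). A bound uses levels per channel after loess and between-array quantile normalization of the mean brightness, and takes the higher of the dim probe's own level and the lowest level above background. It allows for the detection limit only, not for the spread between arrays. Where it exceeded the fitted fold, only the direction is given. Means over lists and runs, the values over single ways round the loop and the figures use fitted values of such probes too, so they rest in part on signals at the floor.

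Before the data were examined, 26 gene lists, the rule for named genes, the tests and most alternatives were fixed. Of the lists, 23 are defined by product text and could not be tested without product names. The other 3 are runs of locus tags: Csac_2404 to Csac_2411, Csac_1076 to Csac_1080 and Csac_2437 to Csac_2439. They were tested with camera at a preset correlation between genes of 0.01. The log2 differences of adjacent tags correlated at 0.246 to 0.44, so the preset may be too low for runs and these p-values too small. An alternative estimated the correlation from the data, on 1 residual degree of freedom. Its adjusted p was 0.421 or more for every list and comparison, even at a list mean of 3.85. It could hardly pass and cannot decide for or against a list. The rule for named genes took, per comparison, the 6 highest and 6 lowest genes past the threshold whose 2 ways round the loop had the same sign, plus up to 2 past-threshold members of each list. Where fewer than 6 passed, the places were filled by size among probes above background in at least 1 of the compared substrates. Because the tags have no names here, at most 2 higher and 2 lower of them are printed per comparison, beside list members. Runs of at least 3 consecutive tags past the threshold in one direction were chosen after the values were seen. By convention locus tags are numbered along the chromosome. No positions were used.

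The procedure was tested on simulated loops of 2793 genes with a dye effect in each gene, in which 50 genes at each of 4 sizes differed on xylan. For xylan vs glucose, 0 of 50 were recovered at a log2 size of 1, 26 at 2, 50 at 3 and 50 at 4. For xylan vs xylose, which share no array, the numbers were 0, 8, 40 and 50. None of the 2593 unchanged genes was called in either comparison. The simulated errors were independent between genes, equally spread on every array and sized from the moderated variances of the fit. Moderation pulls those variances towards a shared value, so the simulated genes differed less in spread than the model assumes. These numbers therefore hold only for such errors. The measured arrays differed in spread and neighbouring tags correlated, as given below, so the error rate on them was not tested. Alternatives covered the background correction, the normalization within and between arrays, the summary of the spots, dim probes, an intensity trend in the variance, a 2-fold minimum, spots kept apart, separate channels, the series table and leaving out each array. The number of arrays limits the precision. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.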

Results

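Transcript levels of Caldicellulosiruptor saccharolyticus were compared after growth on 5 substrates found in plant cell walls: the sugars glucose and xylose, the polysaccharides xylan (a xylose polymer) and xyloglucan (a glucan with xylose side chains), and the oligosaccharides made from xyloglucan. The series was designed to find the sugar transporters and the central carbon pathways used on each substrate. The 5 arrays gave 10 channels, 2 per substrate. The signal over the empty spots differed between channels: the median probe was 3.77 times as bright as the median empty spot in the xyloglucan oligosaccharides channel of the array shared with xylose, but 1.19 times in the xylan channel of the array shared with xyloglucan. The number of the 2793 probes above background ran from 1048 in that xylan channel to 2347 in the glucose channel of the array shared with xylan. Both channels of a substrate were above background for 2097 probes on glucose, 1852 on xylose, 1490 on xyloglucan oligosaccharides, 1204 on xyloglucan and 962 on xylan.

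Over all 5 substrates, 102 genes differed (moderated F test of limma, Benjamini-Hochberg adjusted), and 396 had an unadjusted p below 0.05. Of the 102 genes, 55 had their lowest level on xylan and 35 their highest level on glucose. The fit assumes 1 spread for all arrays, but the ratios of the glucose and xylan array spread more widely (SD 1.04 against 0.61 to 0.71). That may raise both counts. Xyloglucan was the highest substrate for 23 and the lowest for 1. Xylan was the highest for 18, xylose for 15 and xyloglucan oligosaccharides for 11. Without a test, 554 genes were at least 2-fold apart between xylan and glucose, 175 between xylose and glucose, 345 between xyloglucan and glucose and 233 between xyloglucan oligosaccharides and glucose. The counts were 511 for xylan vs xylose, 372 for xyloglucan oligosaccharides vs xyloglucan, 227 for xyloglucan vs xylan and 195 for xylose vs xyloglucan oligosaccharides. The counts past the threshold, given below, rest on 1 residual degree of freedom moderated across probes. When the test was restricted to the 1272 probes above background on every array, the prior degrees of freedom fell from 9.59 to 3.96 and 0 genes passed in any comparison.

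On xylan relative to glucose, 40 genes were higher and 93 lower, and all 133 differed by at least 2-fold. The balance depended on the test: without one, 277 genes were at least 2-fold higher and 277 lower, 356 were higher and 363 lower with separate channels, and 177 and 206 with an intensity trend in the variance. The run Csac_0679 to Csac_0681 rose together, by a mean log2 of 5.76 over its 3 genes (largest adjusted p = 0.00248), or 2.91 without the array shared by both substrates. Csac_0681 was higher by 6.54 ± 0.87 (SE, n = 2 channels per substrate, adjusted p = 0.00248). Its mean log2 level was 12.57 ± 1.53 (SD, n = 2) on xylan and 7.15 ± 1.76 (SD, n = 2) on glucose, where 1 of the 2 channels was above background. Csac_0679 was not above background on glucose and was at least 20.2-fold higher on xylan (adjusted p = 0.00222). Of the genes that fell, Csac_1032 had a log2 difference of -4.69 ± 0.47 (adjusted p = 0.000679) and Csac_1021 of -4.15 ± 0.49 (adjusted p = 0.00222). Both were above background in 1 of the 2 xylan channels, so the sizes rest in part on the floor.

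Of the 5 genes of the run Csac_1076 to Csac_1080, known in this species for multidomain glucanases and mannanases (an annotation from outside the files), 4 rose on xylan relative to glucose. Adjusted over the list alone, 5 passed. Csac_1076 was not above background on glucose and was at least 21-fold higher on xylan (adjusted p = 0.000568). Csac_1080 was higher by 4.67 ± 0.58 (adjusted p = 0.00233), Csac_1079 by 3.97 ± 0.52 (adjusted p = 0.00248) and Csac_1077 by 2.58 ± 0.47 (adjusted p = 0.0118). On glucose, Csac_1080 was above background in 1 of the 2 channels. Csac_1078 differed by 2.62 ± 0.67 and missed the threshold (adjusted p = 0.0536). The mean log2 difference of the list was 3.85, or 2.01 without the array shared by xylan and glucose (camera adjusted p = 1.34e-09, adjusted p = 0.536 with an estimated correlation). None of the 8 genes of Csac_2404 to Csac_2411, a run known for xylan-degrading enzymes by the same outside annotation, passed the threshold in any of the 8 comparisons, over all genes or adjusted over the list alone. Their mean log2 difference for xylan relative to glucose was 0.4 (camera adjusted p = 0.186), and over all 8 comparisons the camera adjusted p ran from 0.121 to 0.973. On xylan 1 of the 8 was above background in both channels and 3 in neither. The mean log2 level there was 9.52 for Csac_2405 and 7.44 to 8.19 for the other 7. On glucose 6 of the 8 were above background in both channels. The largest difference for xylan relative to glucose was 0.79 ± 0.46 (Csac_2411, adjusted p = 0.435).

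**Figure D1:**
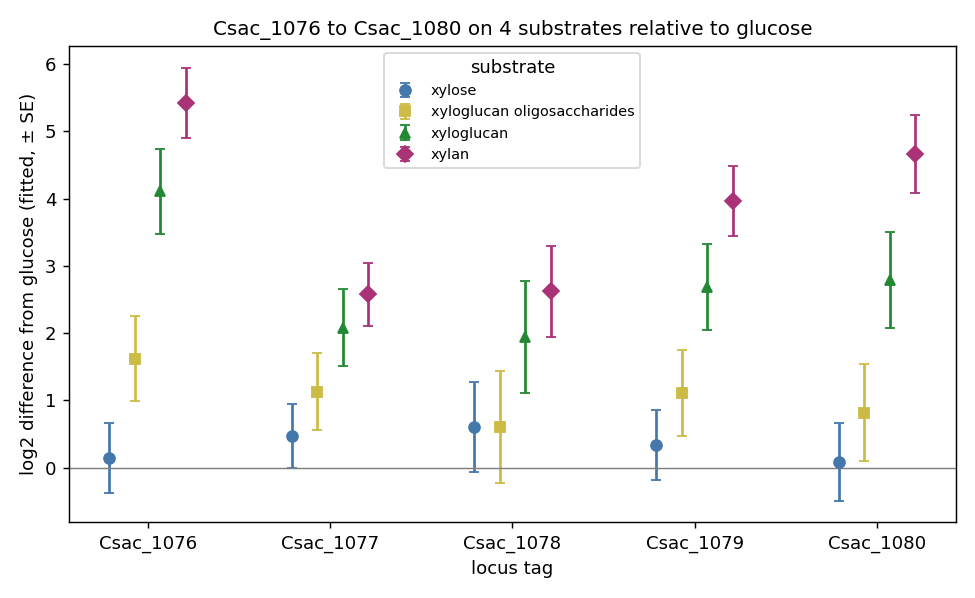
Fitted log2 difference from glucose (vertical axis) of the 5 genes Csac_1076 to Csac_1080 (horizontal axis) on xylose, xyloglucan oligosaccharides, xyloglucan and xylan, with bars of ± 1 SE. Values on xylan run from 2.58 to 5.43, on xyloglucan from 1.94 to 4.11 and on xylose from 0.09 to 0.6.

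Of the genes lower on xylan than on glucose, 6 runs of at least 3 consecutive locus tags fell. Csac_1458 to Csac_1460 had a mean log2 difference of -3.27. The 5 genes of Csac_1860 to Csac_1864 had a mean of -2.91, Csac_1303 to Csac_1305 of -2.69 and Csac_2207 to Csac_2209 of -2.48. Csac_2124 to Csac_2126 had a mean of -2.33 and Csac_1698 to Csac_1700 of -2.29, with a largest adjusted p over these 6 runs of 0.0487. Of the 133 genes, 130 went the same way on the array shared by xylan and glucose and over the other 4 arrays, against 55.2% of all probes. The difference between the 2 ways is the error of the test, so the test favours such genes. The sizes differed for several named genes: without the shared array, Csac_0681 was at 1.72, Csac_0679 at 2.36, Csac_1080 at 2.32, Csac_1079 at 2.37 and Csac_1078 at -0.59.

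**Figure D2:**
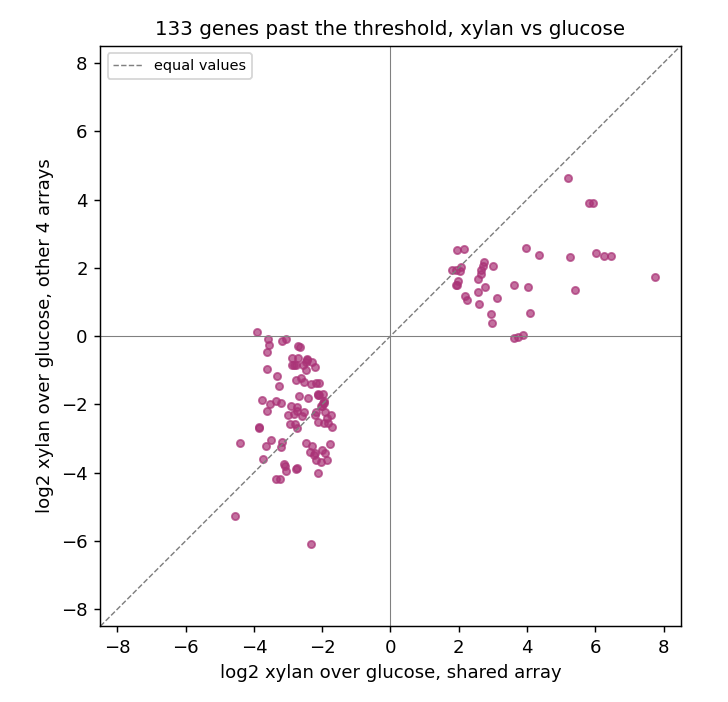
Log2 xylan over glucose of the 133 genes past the threshold, measured on the array shared by both substrates (horizontal axis) and over the other 4 arrays (vertical axis); each point is a gene and the dashed line marks equal values. 130 of 133 points have the same sign on both axes, which the test itself favours because it takes the difference between the axes as its error. Csac_0681, at 7.75 on the shared array and 1.72 over the others, lies far from the line.

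On xylose relative to glucose, 3 genes were higher and 20 lower. The neighbours Csac_0241 and Csac_0240 rose by 4.67 ± 0.51 (adjusted p = 0.00651) and 4.29 ± 0.60 (adjusted p = 0.0124) on the log2 scale. The mean log2 level of Csac_0241 was 13.11 ± 1.05 (SD, n = 2) on xylose and 7.79 ± 0.38 (SD, n = 2) on glucose. On glucose, Csac_0240 was above background in 1 of the 2 channels. Csac_1329 was not above background on xylose and was at least 14.7-fold lower than on glucose (adjusted p = 0.0101). Csac_1021, which also fell on xylan, had a log2 difference of -4.07 ± 0.49 (adjusted p = 0.00754). In each of the runs Csac_1698 to Csac_1700 and Csac_2124 to Csac_2126, 2 of the 3 genes fell, and the run means were -2.16 and -2.69. None of Csac_1076 to Csac_1080 passed, over all genes or adjusted over the list alone (mean 0.33, or -0.13 on the shared array and 2.17 over the others, camera adjusted p = 0.284). The 3 genes of Csac_2437 to Csac_2439, known for a fructose phosphotransferase system by outside annotation, had a mean of -0.83, with 0 past the threshold, 0 adjusted over the list alone, and a camera adjusted p of 0.0154. With an estimated correlation the adjusted p was 0.649, and against all runs of as many consecutive tags it was 0.156. Over all probes, 44.8% had the same sign on both ways round the loop, against 46.2% to 57% in the other comparisons. Of the 250 probes at least 2-fold apart on the array shared by xylose and glucose, 53.6% went the same way over the other 4 arrays. The 95% exact binomial interval, taking genes as independent, was 47.2 to 59.9, and the median over those 4 arrays was 0.09. The arrays as a whole thus did not agree on this comparison. A constant dye effect enters the 2 ways with opposite signs and was not separated from such disagreement. Without the array shared by xylose and glucose, Csac_0240 was at 6.79 and Csac_1329 at -2.25. Neither passed without background correction (adjusted p = 0.0579 for both).

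On xylan relative to xylose, its main monomer, 12 genes were higher and 19 lower. Csac_0679 to Csac_0681 rose by a mean log2 of 4.79, or 2.65 over the longer way round the loop. Csac_0681 was higher by 5.54 ± 1.07 (adjusted p = 0.0312). Of Csac_1076 to Csac_1080, 3 rose, and 5 passed adjusted over the list alone. Csac_1076 was higher by 5.29 ± 0.63 (adjusted p = 0.00979), Csac_1079 by 3.63 ± 0.64 (adjusted p = 0.0265), and Csac_1080, not above background on xylose, was also higher (adjusted p = 0.0226). On xylose, Csac_1076 and Csac_1079 were each above background in 1 of the 2 channels. The list mean was 3.53, or 4.45 over the shorter way and 2.15 over the longer (camera adjusted p = 6.96e-10, adjusted p = 0.421 with an estimated correlation). Among the genes that fell, Csac_1032 was at -4.42 ± 0.57 (adjusted p = 0.00979) and Csac_2205 at -4.36 ± 0.58 (adjusted p = 0.00979), both above background in 1 of the 2 xylan channels. The runs Csac_1458 to Csac_1460 and Csac_1861 to Csac_1864 fell, with means of -3.52 and -3.34. Csac_2437 to Csac_2439 had a mean of 0.53 relative to xylose (camera adjusted p = 0.204) and of -0.3 relative to glucose (camera adjusted p = 0.507), with 0 genes past the threshold or adjusted over the list alone in either. The 2 substrates share no array, and Csac_0681 was at 7.95 over the shorter way round the loop and 1.93 over the longer. Without background correction 2 genes passed, 0 higher and 2 lower on xylan, so none of the 12 higher genes stayed past the threshold. After median centring in place of loess 20 were higher and 53 lower.

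On xyloglucan relative to glucose no gene passed the threshold. The smallest adjusted p was 0.0672, and 154 genes had an unadjusted p below 0.05. The largest positive values were those of Csac_1358, not above background on glucose and at least 18.7-fold higher (adjusted p = 0.0672), and Csac_0681, at a log2 difference of 4.49 ± 1.07 (adjusted p = 0.192). The largest negative values were those of Csac_2659, at -3.16 ± 0.63, and Csac_1021, at -3 ± 0.60 (adjusted p = 0.134 for both). On xyloglucan, Csac_2659 was above background in 1 of the 2 channels. Csac_0681 was at 0.88 without the glucose and xylan array or the xylan and xyloglucan array, and at 6.9 without any other. Over the same 2 ways Csac_2659 was at -2.01 and -3.93, and Csac_1358 at 7.1 and 3.73. All 5 genes of Csac_1076 to Csac_1080 lay above 0, from 1.94 to 4.11, with 0 past the threshold over all genes and 5 adjusted over the list alone. Csac_1076, not above background on glucose, was at least 4.15-fold higher (adjusted p = 0.0672). The list mean was 2.72, or 3.64 over the shorter way and 1.34 over the longer (camera adjusted p = 6.72e-10, adjusted p = 0.633 with an estimated correlation). Csac_2437 to Csac_2439 had a mean of 0.2 (camera adjusted p = 0.719). The count of 0 changed to 55 with an intensity trend in the variance, to 20 after median centring (13 higher, 7 lower) and to 13 after scaling the arrays to one spread (8 higher, 5 lower).

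On xyloglucan oligosaccharides relative to glucose no gene passed either, with a smallest adjusted p of 0.25 and 106 genes at an unadjusted p below 0.05. Csac_1358 was at least 5.67-fold higher (adjusted p = 0.398) and Csac_0973 had a log2 difference of 3.02 ± 0.57 (adjusted p = 0.253). Csac_2493 had a difference of -3.55 ± 0.59 (adjusted p = 0.25), and Csac_1329, not above background on the oligosaccharides, was lower (adjusted p = 0.356). Over the shorter and the longer way round the loop Csac_1358 was at 4.76 and 1.39. Csac_1076 to Csac_1080 had a mean of 1.06, or 0.13 over the shorter way and 2.44 over the longer, and 0 genes past the threshold, also adjusted over the list alone (camera adjusted p = 0.000686, adjusted p = 0.533 with an estimated correlation). Csac_2437 to Csac_2439 had a mean of -1.58, with 2 genes past the threshold adjusted over the list alone (camera adjusted p = 3.69e-05, adjusted p = 0.425 with an estimated correlation). The count of 0 changed to 41 with an intensity trend in the variance, to 7 after median centring (2 higher, 5 lower) and to 18 after scaling the arrays (9 higher, 9 lower).

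Between xyloglucan and its oligosaccharides, 12 genes were lower on the oligosaccharides and 0 higher. Without a test 139 genes were at least 2-fold higher and 233 lower, and the calls were 72 higher and 140 lower with an intensity trend in the variance and 165 and 252 with separate channels. Csac_2493 fell by 4.67 on the log2 scale (SE 0.48, adjusted p = 0.00363) and Csac_0221 had a difference of -3.71 ± 0.50 (adjusted p = 0.0177). Csac_2439, of the run Csac_2437 to Csac_2439, had a difference of -3.34 ± 0.46 (adjusted p = 0.0177). Csac_2437 and Csac_2438 were at -0.97 and -1.04 and did not pass, and 1 of the 3 passed adjusted over the list alone. The mean of this list was -1.78 (camera adjusted p = 0.00035, adjusted p = 0.451 with an estimated correlation). The largest positive values, Csac_0977 at 2.59 ± 0.49 (adjusted p = 0.0559) and Csac_2369 at 2.43 ± 0.61 (adjusted p = 0.136), did not pass. On xyloglucan, Csac_0977 was above background in 1 of the 2 channels. Csac_1076 to Csac_1080 had a mean of -1.67, or -3.51 without the shared array, with 0 genes past the threshold and 3 adjusted over the list alone (camera adjusted p = 5.61e-05, adjusted p = 0.451 with an estimated correlation). Without the array shared by these substrates Csac_0221 was at -2.45, Csac_2369 at 5.09 and Csac_2438 at -0.38. The count of 12 was 6 without background correction, 37 after median centring and 39 after scaling the arrays (6 higher, 33 lower).

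Between the polysaccharides, 32 genes were higher on xyloglucan than on xylan and 1 was lower. Csac_1358 was not above background on xylan and was at least 8.89-fold higher on xyloglucan (adjusted p = 0.0102). Csac_2493 was higher by 4.09 ± 0.48 (adjusted p = 0.00639), and Csac_1458 to Csac_1460 rose by a mean of 2.92. On xylan, Csac_2493 was above background in 1 of the 2 channels, with a mean log2 level of 9.68 ± 2.54 (SD, n = 2). Csac_1680 was the gene that fell, with a difference of -2.68 ± 0.52 (adjusted p = 0.0351). Csac_0178, not above background on xyloglucan, was lower and did not pass (adjusted p = 0.127). Csac_1076 to Csac_1080 had a mean of -1.13, or -2.97 without the array shared by both polysaccharides, with 0 genes past the threshold and 1 adjusted over the list alone (camera adjusted p = 0.000122, adjusted p = 0.466 with an estimated correlation). Against all runs of as many consecutive tags the adjusted p was 0.0669. Csac_2437 to Csac_2439 had a mean of 0.5 and a median of -0.1, with 1 gene past the threshold adjusted over the list alone (camera adjusted p = 0.27). Without the array shared by xylan and xyloglucan, Csac_1358 was at 7.07 and Csac_1680 at -4.31. The count of 33 was 13 without background correction, Csac_1358 and Csac_1680 not among them, and 67 after median centring.

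On xylose relative to xyloglucan oligosaccharides, 3 genes were higher and 1 lower. The 3 were the consecutive tags Csac_0240 to Csac_0242, with a mean log2 difference of 5.31, or 2.85 without the array shared by these substrates. Csac_0241 was higher by 5.82 ± 0.51 (adjusted p = 0.000771) and Csac_0242 by 5.27 ± 0.70 (adjusted p = 0.0132). Both were above background in 1 of the 2 xyloglucan oligosaccharides channels, so the sizes rest in part on the floor. Csac_0419 was the gene that fell, at -3.15 ± 0.49 (adjusted p = 0.0391). Csac_1358, not above background on xylose and at least 4.5-fold lower, did not pass (adjusted p = 0.0529). Csac_1076 to Csac_1080 had a mean of -0.73 (-2.57 without the shared array) and Csac_2437 to Csac_2439 of 0.75, with 0 genes of either past the threshold or adjusted over the list alone (camera adjusted p = 0.00838 for both). With an estimated correlation the adjusted p was 0.529 for both, and against all runs of as many consecutive tags 0.0797 for both. Without the array shared by these substrates Csac_0242 was at 1.84, Csac_0419 at -2.08 and Csac_1358 at -0.91. The count of 4 was 1 without background correction, when neither Csac_0242 nor Csac_0419 passed, 13 after median centring (6 higher, 7 lower) and 111 after scaling the arrays (36 higher, 75 lower).

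**Figure D3:**
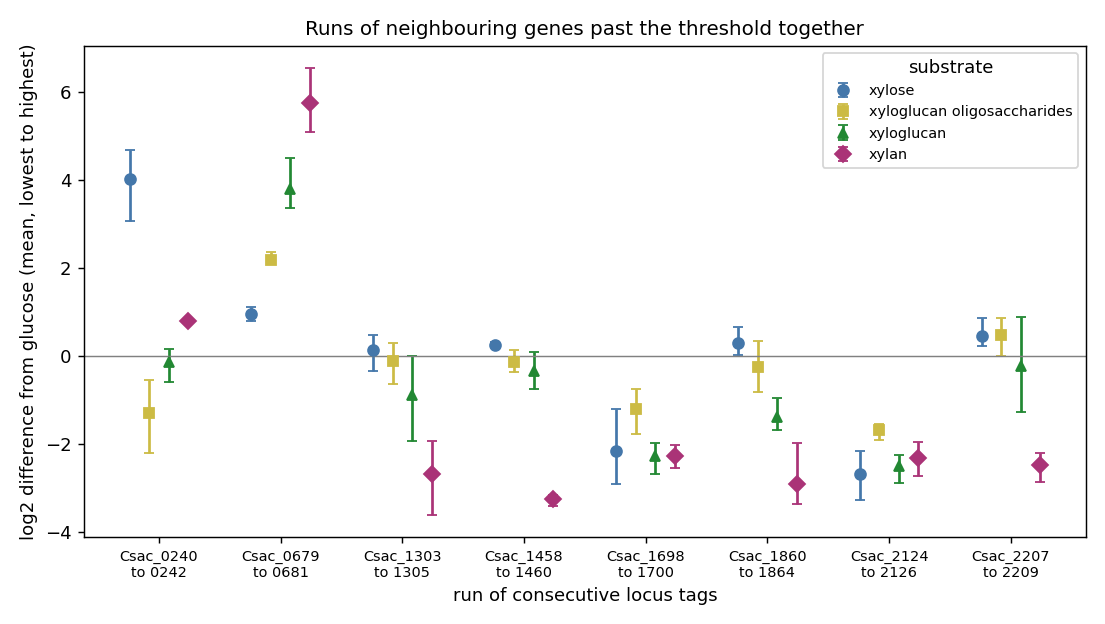
Mean log2 difference from glucose (vertical axis) of 8 runs of consecutive locus tags (horizontal axis) on 4 substrates, with bars from the lowest to the highest gene of a run; each run was chosen because its genes passed the threshold together in at least 1 comparison. Csac_0240 to Csac_0242 are high on xylose, at a mean of 4.01, and between -1.31 and 0.79 on the other 3 substrates. Over the 2 ways round the loop the xylose mean is 3.39 or 6.47.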

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

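The test of the deposited ratios against median-centred ratios was chosen after its result was seen, and that of the empty spots before for the array of xyloglucan and its oligosaccharides and after for the other 4. Spots named as empty entered no comparison, and they were brighter than the local background around them in every channel of every array. The median of the empty spots was 11.8 times the median local background in the xyloglucan oligosaccharides channel of the array shared with xyloglucan, against 2.54 times in the xyloglucan channel of that array. On the array of xyloglucan oligosaccharides and xylose the values were 3.63 and 3.51. They were 4.73 for xylose and 2.71 for glucose on the array those 2 shared, and 2.85 for glucose and 4.01 for xylan on the next. On the array of xylan and xyloglucan they were 4.77 and 3.7.

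The deposited log2 ratios of xyloglucan over xyloglucan oligosaccharides rose with probe brightness, with a rank correlation across probes of 0.782, against 0.08 after loess. When the empty-spot median of each channel was subtracted and no loess applied, the rank correlation fell to 0.149, as it would if the uneven glow of the empty spots caused it. On the other 4 arrays, in the order above, the deposited ratios had rank correlations of -0.428, -0.716, 0.269 and -0.667, and after the same subtraction -0.0722, 0.0783, 0.0762 and -0.201. The array of xyloglucan oligosaccharides and xylose had nearly even empty spots and still the -0.428, so uneven empty spots of its own do not explain that trend. The trend there fell with the subtraction as well, and the loop fit passes a trend of 1 array on to the others. The falls therefore cannot tell whether uneven empty spots caused the trends. The deposited ratios correlated at 0.991 across probes with scanner ratios that were centred on their median and fitted over the loop, without loess, and a table made without intensity-dependent normalization is consistent with that value. Genes are not independent replicates in these correlations. No biological explanation was tested.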

How the results depend on the processing

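The empty-spot background, the separate-channel fit without a dye term, the restriction to probes above background in both compared substrates and the comparison with all runs of consecutive tags were chosen after seeing the data, and the others before. The counts of genes past the threshold depended on the processing in every comparison. None of the genes named by the rule and printed above reversed its direction under the alternatives run on it. For genes past the threshold this says nothing about leaving out an array, because the rule took only genes with the same sign on both ways round the loop. Of the list members, several had opposite signs over the 2 ways round the loop. For Csac_1076 to Csac_1080 these were 4 of 5 for xylose vs glucose, 2 for xyloglucan oligosaccharides vs glucose (Csac_1078 at -1.01 and Csac_1080 at -0.36 over 1 way) and 1 for 5 other comparisons. Csac_1078 was at -0.59 over 1 way for xylan vs glucose, -0.47 for xyloglucan vs glucose and -0.39 for xylan vs xylose. For Csac_2404 to Csac_2411 they were from 3 to 6 of 8 per comparison, and for Csac_2437 to Csac_2439 1 of 3 for xylan vs glucose and for xyloglucan vs xylan. Of the 36 named results that were rerun, 9 of those past the threshold lost it without background correction. With median centring, with separate channels and with the empty-spot background 12 gained it, each time all of those not past it. The files carry no spot flags, so keeping flagged spots was not run. The planned separate-channel fit with a dye term could not be fitted, because it leaves no residual degree of freedom for the ratios. Except where stated, the cause of a change was not tested. The ratios use the pairing of 2 substrates on an array. No further paired analysis was possible because no pair of substrates shares more than 1 array and the labels give no replicate numbers. Signal over background limits the xylan and xyloglucan channels most: on the array they share, 37.5% and 43.4% of probes were above background.

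Counts that moved by more than 1.5 times were as follows. Without background correction 52 genes passed over all 5 substrates, 14 for xylose vs glucose, 2 for xylan vs xylose, 6 for xyloglucan oligosaccharides vs xyloglucan, 13 for xyloglucan vs xylan and 1 for xylose vs xyloglucan oligosaccharides, and 152 genes were 2-fold apart for xyloglucan oligosaccharides vs glucose, 331 for xylan vs xylose, 164 for xyloglucan oligosaccharides vs xyloglucan and 122 for xyloglucan vs xylan. With plain background subtraction 39 passed for xylose vs glucose and 8 for xylose vs xyloglucan oligosaccharides. After median centring in place of loess 236 passed over all 5 substrates, 40 for xylose vs glucose, 20 for xyloglucan vs glucose, 7 for xyloglucan oligosaccharides vs glucose, 73 for xylan vs xylose, 37 for xyloglucan oligosaccharides vs xyloglucan, 67 for xyloglucan vs xylan and 13 for xylose vs xyloglucan oligosaccharides. After scaling between arrays the counts, in the order all 5 substrates, xylose, xylan, xyloglucan and xyloglucan oligosaccharides vs glucose, xylan vs xylose, xyloglucan oligosaccharides vs xyloglucan, xyloglucan vs xylan and xylose vs xyloglucan oligosaccharides, were 253, 70, 87, 13, 18, 73, 39, 56 and 111. In the same order they were 448, 83, 383, 55, 41, 184, 212, 115 and 80 with an intensity trend in the variance. They were 2163, 956, 1596, 1187, 1065, 1360, 1480, 1051 and 927 with the spots kept apart and a dye term added, which changes 2 choices at once: the error is then the spread between spots of an array, and the dye term takes up the closure of the loop. They were 706, 120, 719, 111, 51, 349, 417, 185 and 117 with separate channels without a dye term. With the empty-spot background 273 passed over all 5 substrates, 45 for xylose vs glucose, 32 for xyloglucan vs glucose, 8 for xyloglucan oligosaccharides vs glucose, 88 for xylan vs xylose, 98 for xyloglucan oligosaccharides vs xyloglucan, 74 for xyloglucan vs xylan and 19 for xylose vs xyloglucan oligosaccharides, and 587 were 2-fold apart for xyloglucan oligosaccharides vs xyloglucan. With the median of the spots 19 passed for xylan vs xylose and 7 for xyloglucan oligosaccharides vs xyloglucan.

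With only the 1272 probes above background on every array, limma called 0 genes over all 5 substrates, 0 for xylose vs glucose, 0 for xylan vs glucose, 0 for xylan vs xylose, 0 for xyloglucan oligosaccharides vs xyloglucan, 0 for xyloglucan vs xylan and 0 for xylose vs xyloglucan oligosaccharides. For xylan vs glucose 285 of them had an unadjusted p below 0.05, the smallest adjusted p was 0.0776, and 103 of the 133 genes were among them. The prior degrees of freedom were 3.96 in place of 9.59. Of these probes, 145 were 2-fold apart for xyloglucan oligosaccharides vs glucose and 222 for xyloglucan oligosaccharides vs xyloglucan. With only probes above background in both compared substrates 1 gene passed for xyloglucan oligosaccharides vs xyloglucan, 1 for xylose vs xyloglucan oligosaccharides, and 0 for xylose vs glucose, xylan vs glucose, xylan vs xylose and xyloglucan vs xylan.

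Leaving out 1 array leaves no error estimate, so only values without a test remain. The number of genes 2-fold apart ranged from 250 to 1008 for xylose vs glucose, 649 to 1022 for xylan vs glucose, 672 to 679 for xyloglucan vs glucose, 457 to 865 for xyloglucan oligosaccharides vs glucose, 750 to 845 for xylan vs xylose, 380 to 1184 for xyloglucan oligosaccharides vs xyloglucan, 227 to 1141 for xyloglucan vs xylan and 221 to 1098 for xylose vs xyloglucan oligosaccharides. The highest value came without an array that the compared substrates share, where they share one. In the authors' deposited ratios, 551 genes were 2-fold apart for xyloglucan oligosaccharides vs glucose and 889 for xyloglucan oligosaccharides vs xyloglucan.

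For gene lists, the adjusted p for Csac_1076 to Csac_1080 with an estimated correlation, which rests on 1 residual degree of freedom, was 0.536 for xylan vs glucose, 0.633 for xyloglucan vs glucose, 0.533 for xyloglucan oligosaccharides vs glucose, 0.421 for xylan vs xylose, 0.451 for xyloglucan oligosaccharides vs xyloglucan, 0.466 for xyloglucan vs xylan and 0.529 for xylose vs xyloglucan oligosaccharides. For Csac_2437 to Csac_2439 it was 0.649 for xylose vs glucose, 0.425 for xyloglucan oligosaccharides vs glucose, 0.451 for xyloglucan oligosaccharides vs xyloglucan and 0.529 for xylose vs xyloglucan oligosaccharides. No list passed in any comparison with an estimated correlation, whatever its mean difference, so these values cannot decide for or against a list. Against all runs of as many consecutive tags, Csac_1076 to Csac_1080 no longer passed for xyloglucan vs xylan (0.0669) and xylose vs xyloglucan oligosaccharides (0.0797), nor Csac_2437 to Csac_2439 for xylose vs glucose (0.156) and xylose vs xyloglucan oligosaccharides (0.0797). Csac_1076 to Csac_1080 still passed for xylan vs glucose (0.00334), xyloglucan vs glucose (0.00111) and xyloglucan oligosaccharides vs glucose (0.0273). It also passed for xylan vs xylose (0.00111) and xyloglucan oligosaccharides vs xyloglucan (0.00668). Csac_2437 to Csac_2439 passed for xyloglucan oligosaccharides vs glucose (0.0223) and vs xyloglucan (0.00668). These values lie far above those of camera at the preset correlation. On ranks, Csac_2404 to Csac_2411 passed for xyloglucan vs xylan (0.0315).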

Other observations

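The 3 tests of the excess of genes between xylan and glucose were chosen after their results were seen, and that of dim probes was run in 3 forms, all given below. The 2 tests of place and brightness of neighbouring tags were chosen before for xylan vs glucose and after for the other comparisons. Csac_1698 to Csac_1700 and Csac_2124 to Csac_2126 lay below glucose on all 4 other substrates: the means of the first were -2.16 on xylose, -2.29 on xylan, -2.29 on xyloglucan and -1.22 on xyloglucan oligosaccharides, and those of the second -2.69, -2.33, -2.51 and -1.69. The values on xyloglucan and on xyloglucan oligosaccharides did not pass the threshold for any gene of either run. Csac_0679 to Csac_0681 had means of 0.96 on xylose, 2.18 on xyloglucan oligosaccharides, 3.8 on xyloglucan and 5.76 on xylan relative to glucose. All 3 genes passed on xylan and 0 on the other substrates. Over the 2 ways round the loop the means were 0.25 or 3.81, 0.76 or 4.32, 5.23 or 1.67 and 6.47 or 2.91. A constant dye effect also separates the 2 ways and cancels only in the fitted means. The single ways therefore cannot tell whether the arrays disagree on the order. Csac_1458 to Csac_1460 had means of 0.25 on xylose, -0.15 on xyloglucan oligosaccharides and -0.34 on xyloglucan, against -3.27 on xylan. The 2 values on xyloglucan and its oligosaccharides turned positive when the arrays were scaled to one spread. Relative to glucose on xyloglucan, the 5 genes of Csac_1860 to Csac_1864 lay close, from -1.69 to -0.97, while those of Csac_2207 to Csac_2209 ran from -1.29 to 0.88 and those of Csac_1303 to Csac_1305 from -1.95 to 0. These runs were singled out after their values were seen.

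More genes differed between xylan and glucose than in any other comparison, 133 against at most 33. Of the 649 probes at least 2-fold apart on the array shared by xylan and glucose, 67.2% went the same way over the other 4 arrays (95% exact binomial interval 63.4 to 70.8, taking genes as independent). These differences were thus not on that array alone. On the other arrays the share ran from 53.6% (xylose and glucose) over 67% (xyloglucan oligosaccharides and xylose) and 71.3% (xyloglucan and its oligosaccharides) to 79.3% (xylan and xyloglucan). Arrays without an excess had like shares, so the share cannot tell whether that array is the source of the excess. For xylan and glucose the median size was 1.5 on the shared array and 0.57 over the others. Whether dim probes account for it cannot be told from these values, because 3 forms of the test disagreed. Among probes above background on every array, 432 were 2-fold apart for xylan vs glucose and 352 for xylan vs xylose, the next comparison, a ratio of 1.23. Against xylose vs glucose the ratio was 3.63. Of the genes past the threshold, 103 for xylan vs glucose and at most 32 in another comparison were among these probes, a ratio of 3.22, but those calls use an error estimate shared with the dim probes, and a refit on these probes alone called 0 genes in every comparison. A wider spread of ratios on that array (SD 1.04 against 0.61 to 0.71 on the others) may account for the excess, since with all arrays scaled to one spread 87 genes passed for xylan vs glucose and 111 for xylose vs xyloglucan oligosaccharides; whether the wider spread comes from growth on xylan or from the hybridisation stays open.

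Genes with neighbouring locus tags changed together. For xylan vs glucose, 31 pairs of adjacent tags passed in the same direction, against a mean of 3.58 and a highest count of 12 in 10000 permutations (p = 1e-04, the smallest they can give). The numbers were 4 for xylose vs glucose, 9 for xylan vs xylose and 9 for xyloglucan vs xylan (permutation p = 1e-04 for each). For xyloglucan oligosaccharides vs xyloglucan there were 0 among 12 genes, too few to tell, with 0.0519 expected. Across 2617 pairs of adjacent tags not printed side by side, the log2 differences for xylan vs glucose correlated at 0.406, and at 0.246 to 0.44 over the 8 comparisons. Between 4902 pairs of probes on neighbouring spots with distant tags the correlation was 0.025 for xylan vs glucose, and at most 0.0825 in any comparison. Between pairs matched in brightness it was 0.0166 on average for xylan vs glucose (highest of 200 draws 0.067), and no draw in any comparison passed 0.0981. A place on directly neighbouring spots therefore does not account for it, while larger areas of the array were not tested. Loess had already removed most of any brightness trend, so pairs matched in brightness could hardly correlate. That test shows only that no such trend was left in the fitted values. Shared transcription of neighbouring genes may be the cause, as a hypothesis, and cross-hybridisation between similar neighbouring genes was not tested, since no probe sequences were used here.

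The closure of the loop, the sum of the 5 ratios of a probe divided by 5, had an SD across probes of 0.269. The spread between the 5 spots of a probe alone would give 0.0858. The comparisons above use the closure, not the spots, as the error. Moderation pools it mostly over all probes, with prior degrees of freedom of 9.59 against 1 residual. A printed SE is therefore largely a shared value and not the spread of the gene itself.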
